A study of Homo sapiens with 7 samples.

How the data were processed

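RNA from 7 formalin-fixed, paraffin-embedded human lung samples was extracted with an isolation kit for fixed tissue, made into stranded total RNA libraries and sequenced as 50-cycle single reads on an Illumina HiSeq instrument, per the labels' protocols. Groups came from the labels' subject status, 3 EGPA and 4 control, and replicates were numbered within a group by order of listing, which pairs nothing. Each sample carried a different subject label.

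The submitters' processing notes name FastQC, kallisto and DESeq2. Their versions, the transcript index and the genome build are not given in the sources used here. Each deposited file listed 104817 transcripts with an estimated count (the expected number of reads, which need not be whole), a TPM value (transcript abundance scaled by the authors' software for effective length and depth) and an effective length, per the file headers. The effective lengths were identical in all files. Because kallisto divides reads that match several transcripts in proportion to their estimated abundances, counts of near-identical genes such as the IgG subclasses, C4A and C4B or SFTPA1 and SFTPA2 are less certain than their totals.

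Transcripts were matched to genes of the GENCODE 29 annotation (GRCh38), from which all coordinates were taken. By identifier, 95600 transcripts (91.2%) matched, 94033 of them with the same version. A further 8346, on alternative haplotypes, were assigned through the gene symbol, and 871 matched no gene and stayed out of library sizes and tests. These held 0.339% to 0.438% of the counts in the controls and 0.374% to 0.694% in EGPA. Genes on chromosome Y, XIST and TSIX were left out of every test. Estimated counts were summed per gene and rounded to whole numbers. Total estimated counts per library were 4443877, 1777557 and 7784350 in EGPA replicates 1 to 3 and 6133315, 6320495, 8431477 and 7610133 in Control replicates 1 to 4. Genes with at least 5 counts numbered 12773, 8306 and 15028 in EGPA and 14966 to 15241 in control. No pair of replicates held identical values, and the lowest chi-square per degree of freedom over the 9 pairs within groups was 27.0, so no library was counted as a copy of another. Labels do not say how the tissue was sampled, and p-values measure the spread between these samples.

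Genes were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F-test on a group design without covariates) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are EGPA over control, with standard errors, and CPM values are normalized with TMM. TMM factors allow CPM to exceed its nominal sum where a gene takes most counts. Of 42 gene lists fixed before the data were examined, 41 had at least 4 tested members and were tested with camera (limma 3.58.1, preset correlation of 0.01), with fry and with camera using an estimated correlation. A member is said to rise or fall only past the threshold over all genes. Shares of counts were compared with two-sided exact permutation tests over the 35 splits (scipy 1.17.1, which doubles the smaller tail), and shares of a library carry exact Clopper-Pearson 95% intervals. Folds against a group at 0 used a floor of 3 counts over the group.

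Named genes followed a rule fixed beforehand: the 10 largest rises and 10 largest falls among called protein-coding or immunoglobulin constant genes with mean log2 CPM of at least 2 and non-overlapping groups, the 4 members with the smallest p of each called list, and a fixed set of immunoglobulin, eosinophil, type 2, regulatory and lung cell genes. Variable segments, polymorphic HLA genes and genes with common whole-gene deletions were not named. One further gene, tested with the rest and counted in its list, is not reported here.

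The scripts were tested on simulated counts drawn from the control means and these libraries' sizes and dispersions, each gene independently of the others. Of 50 genes changed 16-fold, 26 were called, of 50 changed 8-fold 7, of 50 changed 4-fold 1 and of 50 changed 2-fold 0, with 0 of 13699 unchanged genes called among the 13899 of that step. A list of 15 genes changed 4-fold was called with 0 of 40 unchanged lists, among 13928 genes. The adjustment over all genes is stricter when few genes change, and 1748 were called in the real fit. The simulated shares called therefore do not give the power there. The simulation held no correlation between genes and no GC trend, so its false calls do not give the error rate in the real libraries. There, splits of the samples other than the real one called 2 to 25 lists. Alternatives fixed beforehand covered DESeq2 1.42.0 size factors and Wald test, library totals, low-count filters, gene classes left out, a length offset, the number at the end of each sequencing file's name as a factor (read as a lane number, an assumption behind each mention of a lane), limma-voom with quality weights, limma on log2 TPM with pseudocounts of 1 and 0.1, a fold threshold of 1.5, robust fitting and leaving out each replicate. Alternatives added after seeing the data removed a smooth trend with GC content (with or without transcript length) from each library, left out ZFHX3, or kept only EGPA replicate 3 of the EGPA group, a fit that assumes the lone library to vary as the controls do. Lane 3 held only EGPA replicates 1 and 2 and lane 4 only controls, so lane 5 alone gave values of both groups.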

Results

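RNA was sequenced from 7 samples of formalin-fixed, paraffin-embedded human lung, a preservation that fragments RNA. Of these, 3 came from people with eosinophilic granulomatosis with polyangiitis (EGPA), a vasculitis with eosinophil-rich inflammation, and 4 were labelled as controls. Each sample carried its own subject label, and replicates were numbered within each group for naming only. The design text named EGPA against control as the comparison, and the series title directed it at IgG4 plasma cells and immunoregulatory features. The values were transcript counts estimated with kallisto, summed here to genes, and the total per library ran from 1777557 in EGPA replicate 2 to 8431477 in Control replicate 3.

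EGPA replicates 1 and 2 differed from the other 5 libraries in composition. ZFHX3, a homeobox transcription factor gene on chromosome 16 (72782885 to 73891871, GRCh38), held 47.4% of the gene counts in EGPA replicate 1 and 66.9% in EGPA replicate 2, against 1.62% in EGPA replicate 3 and 0.225% to 0.676% in the controls. Nearly all of these counts sat on a single transcript, 99.7% and 99.8% of them in EGPA replicates 1 and 2. The same transcript held 98.8% of the ZFHX3 counts in EGPA replicate 3 and 80.45% to 95.85% in the controls. Outside ZFHX3, EGPA replicate 2 held 585234 counts and EGPA replicate 1 held 2321397, against at least 6067021 in each control. The mean Spearman correlation across genes with the controls was 0.498 for EGPA replicate 1, 0.391 for EGPA replicate 2 and 0.824 for EGPA replicate 3, and it lay between 0.938 and 0.945 for each control with the others (genes are not independent replicates). Deviations of EGPA replicates 1 and 2 from the control mean rose with gene GC content, with Spearman correlations across genes of 0.769 and 0.688, against 0.334 in EGPA replicate 3.

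**Figure D1:**
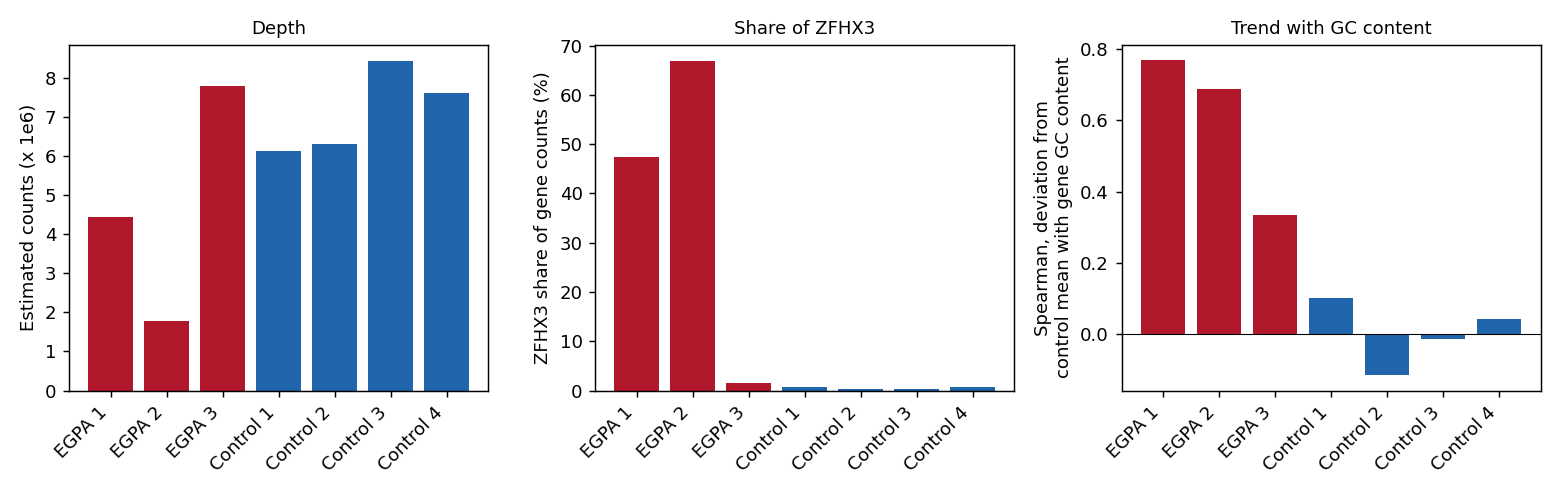
Total estimated counts (left, axis in units of 1e6), the ZFHX3 share of gene counts in percent (middle) and the Spearman correlation across genes between a library's deviation from the control mean and gene GC content (right), 1 bar per library, EGPA in red and control in blue. ZFHX3 took 47.4% and 66.9% of the counts of EGPA replicates 1 and 2, whose deviations also correlated most with GC content.

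IGHG4, the constant region gene of the IgG4 heavy chain, made up a mean of 50.2% ± 5.94 (SD, n = 3) of the IgG heavy constant counts in EGPA lung and 2.41% ± 2.15 (SD, n = 4) in control lung. All 3 EGPA libraries lay above all 4 controls. The share was 57.0% in EGPA replicate 1 (7266 of 12741 counts, exact Clopper-Pearson 95% interval 56.2% to 57.9%), 47.0% in EGPA replicate 2 (764 of 1624, 44.6% to 49.5%) and 46.5% in EGPA replicate 3 (286015 of 615682, 46.3% to 46.6%). Among the controls it ran from 0.484% in Control replicate 1 (5 of 935, 0.174% to 1.24%) to 5.48% in Control replicate 2 (137 of 2501, 4.62% to 6.44%). IGHG1, the main IgG heavy chain gene in the controls, held 32.5% ± 5.73 in EGPA and 60.9% ± 8.64 in control. The two-sided exact permutation p for the IGHG4 share was 0.0571, the smallest that this test, which doubles the smaller tail over the 35 splits, allows, so it could not pass 0.05 for any share (adjusted p = 0.0857 over the 3 shares tested). Within file lane 5 (a number attached to each sequencing file and read here as its lane, which the labels do not state), the only such number with both groups, EGPA replicate 3 stood at 46.5% and Control replicates 2 and 4 at 5.48% and 1.96%. The 4 IgG genes are close copies whose shared reads the estimation divided between them, so each subclass count carries that uncertainty, and the intervals cover counting error only.

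Immunoglobulin heavy and light constant genes together held 3.33% ± 5.33 (SD, n = 3) of all gene counts in EGPA and 0.0567% ± 0.0247 (SD, n = 4) in control. The share was 9.48% in EGPA replicate 3 (95% interval 9.461% to 9.502%), 0.359% in EGPA replicate 1 (0.353% to 0.364%) and 0.133% in EGPA replicate 2 (0.128% to 0.139%), and no control exceeded 0.0829% (0.0806% to 0.0851%). The exact permutation p was 0.0571 (two-sided, adjusted p = 0.0857). The difference in means, 3.27 percentage points, fell to 0.189 without EGPA replicate 3. These shares are of all gene counts, of which ZFHX3 held 47.4% and 66.9% in EGPA replicates 1 and 2, which lowered the shares of these libraries. With ZFHX3 left out of the denominator, a setting chosen after seeing the data, the difference in means was 3.52 points. In lane 5 the share was 9.48% in EGPA replicate 3, 0.0829% in Control replicate 2 and 0.0691% in Control replicate 4. The lambda share of light chain constant counts was 39.9% ± 21.1 (SD, n = 3) in EGPA and 34.2% ± 2.41 (SD, n = 4) in control, a difference of 5.77 percentage points that lay within the spread (exact permutation p = 0.686, two-sided, adjusted p = 0.686). It was 15.7% in EGPA replicate 3 and 54.2% in EGPA replicate 1, and in EGPA replicate 2, with only 32 light chain counts, 49.8% (31.9% to 68.1%). In lane 5 it was 15.7% in EGPA replicate 3 and 33.2% and 34.7% in Control replicates 2 and 4. Without EGPA replicate 1 the difference was -1.37 percentage points, without EGPA replicate 2 it was 0.818 and without EGPA replicate 3 it was 17.9.

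**Figure D2:**
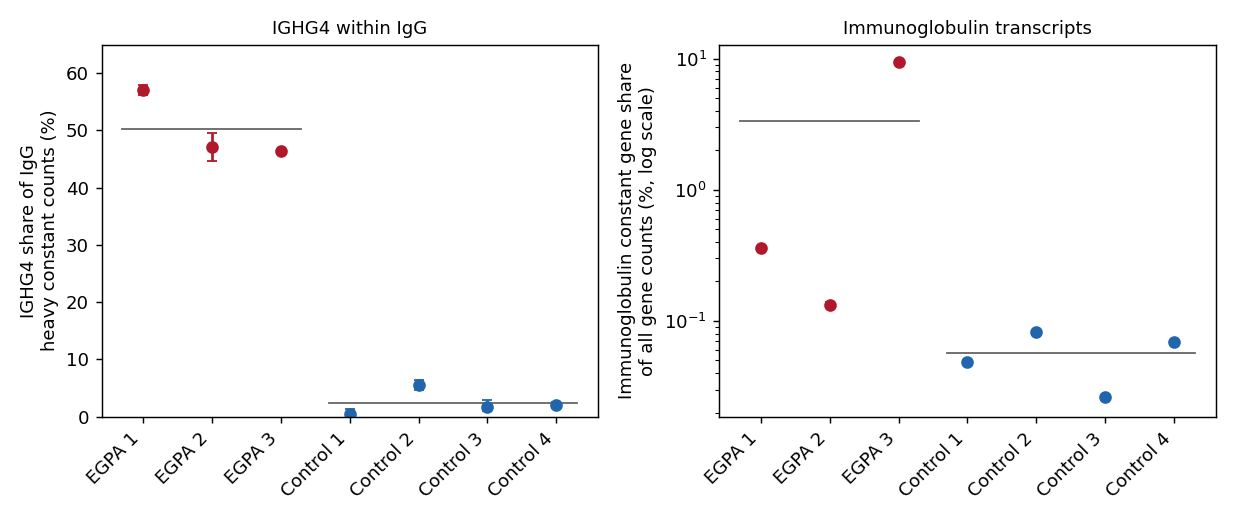
IGHG4 as a percentage of IgG heavy constant counts (left, linear axis) and immunoglobulin constant genes as a percentage of all gene counts (right, log axis) in each library, with exact 95% binomial intervals and grey lines at the group means, EGPA in red and control in blue. The IGHG4 share lay between 46.5% and 57.0% in EGPA and between 0.484% and 5.48% in control, and the immunoglobulin share reached 9.48% in EGPA replicate 3.

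The heavy chain genes rose as a group. Of the 9 tested, 8 rose past an adjusted p of 0.05 in edgeR's quasi-likelihood test, both over all genes and adjusted over the list alone, with a median log2 fold change of 6.01. IGHG4 (chromosome 14, 105620506 to 105626066, GRCh38) had the largest rise of the named genes, 11.03 ± 1.83 (SE) on the log2 scale with an adjusted p of 0.0291, from 0.628 to 15.2 normalized CPM (counts scaled to library size) in the controls to 2916, 1042 and 30694 in EGPA replicates 1 to 3. IGHE (chromosome 14, 105597691 to 105601728), the heavy chain gene of IgE, rose by 9.30 ± 0.80 (adjusted p = 0.0091), from at most 0.333 CPM in any control to 184, 83.2 and 148 CPM. IGHG1, IGHG2, IGHG3 and IGHM rose by 5.08 to 6.36, IGHA2 by 3.97 ± 0.70 and IGHA1 by 2.10 ± 0.52. Several of these rises rested largely on EGPA replicate 3. Without it IGHG3 stood at 2.13, IGHM at 3.02, IGHG1 at 3.11 and IGHG4 at 8.35, while IGHE was at 9.11. With each library's GC trend removed only IGHE passed (7.97, adjusted p = 0.0337). IGHG4 then stood at 10.51, IGHG1, IGHG2, IGHG3 and IGHM at 4.26 to 5.92, IGHA2 at 2.09 and IGHA1 at 1.02, with adjusted p from 0.0513 to 0.41. The list was called by camera with a preset correlation (adjusted p = 9.7e-07) and by fry (adjusted p = 0.0047) but not with an estimated correlation (adjusted p = 0.53).

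Many, but not all, markers of antibody-secreting cells rose with them. Of the 19 plasma cell genes tested, 10 rose past the threshold over all genes and 15 when adjusted over the list alone, and the median log2 fold change was 2.79. POU2AF1, a B-lineage transcriptional coactivator, rose by 6.90 ± 0.78 (adjusted p = 0.0206), MZB1, a chaperone of immunoglobulin assembly, by 6.35 ± 0.94, FCRL5, a surface receptor of B-lineage cells, by 6.40 ± 1.05, DERL3, of the endoplasmic reticulum degradation machinery, by 5.44 ± 0.73, and the kinase gene PIM2 by 4.52 ± 0.70. JCHAIN, which links IgA and IgM multimers, did not pass (4.14 ± 1.36, adjusted p = 0.0730) and had 3000 CPM in EGPA replicate 3 against 46.6 and 40.9 in EGPA replicates 1 and 2 and 26.8 to 76.6 in the controls. Without EGPA replicate 3, POU2AF1, MZB1, FCRL5, DERL3 and PIM2 still stood at 3.38 to 5.96 on the log2 scale, while JCHAIN was at -0.55, CD38 at -1.95, SEC11C at -1.58 and SLAMF7 at 0.11. With the GC trend removed 4 plasma cell genes passed, POU2AF1, FCRL5, PIM2 and IRF4, and MZB1 (5.77) and DERL3 (4.66) did not (adjusted p = 0.0513 for each). Of the 4 light chain constant genes tested, 2 rose, and the list was not called (camera adjusted p = 0.137). Its median difference from the control mean was -0.34 in EGPA replicate 2, and the kappa gene IGKC was at -0.50 without EGPA replicate 3. Among the 8 B cell genes tested, FCER2, the low-affinity IgE receptor gene, rose by 6.27 ± 0.75 and TNFRSF13C, the BAFF receptor gene, by 5.44 ± 1.13, while CD72 (1.21 ± 0.64, adjusted p = 0.206), BACH2 (-0.22) and BANK1 (-0.95) were among those that did not pass. FCER2 and TNFRSF13C rested on 160 and 37 counts over the 3 EGPA libraries. Camera called both lists (adjusted p = 8.6e-08 for plasma cells and 0.0202 for B cells), and neither held with an estimated correlation (adjusted p = 0.89 and 0.53). The B cell call ended without EGPA replicate 3 (adjusted p = 0.193, the highest over 23 alternatives, of which the lowest was 1.8e-05), and fry called the B cell list (adjusted p = 0.0047) but not the plasma cell list (adjusted p = 0.120).

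**Figure D3:**
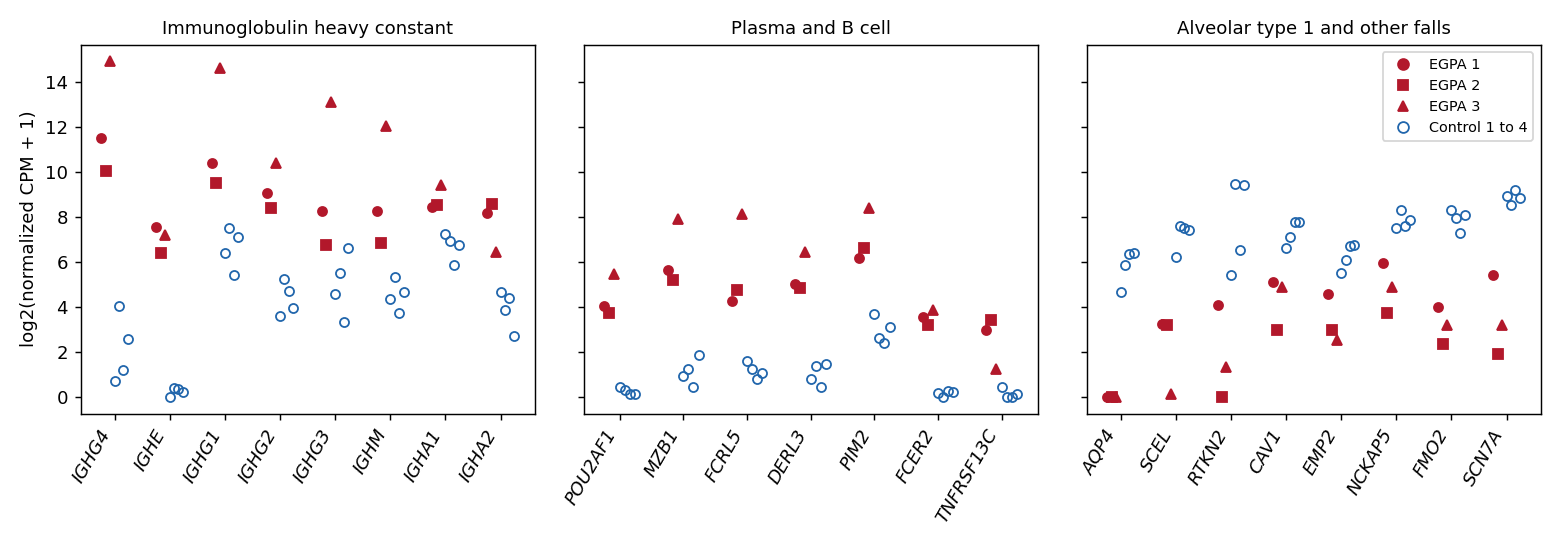
Normalized expression, log2(CPM + 1), of named immunoglobulin, plasma and B cell, and falling genes in each library, with EGPA replicates 1 to 3 as filled red circles, squares and triangles and the 4 controls as open blue circles. IGHG4 and IGHE stood in all 3 EGPA libraries above every control, and AQP4 was at 0 in all 3 EGPA libraries.

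Several genes of alveolar type 1 cells, the thin cells of the gas exchange surface, fell. Of the 14 tested, 5 fell past the threshold and none rose past it, and the list's median log2 fold change was -1.40. Its median difference from the control mean was -0.28 log2 CPM in EGPA replicate 1, within the -0.66 to 0.38 of the controls. In EGPA replicates 2 and 3 it was -3.10 and -3.575. SCEL fell by 4.93 ± 1.17 on the log2 scale, RTKN2 by 5.94 ± 1.54, the caveolin gene CAV1 by 2.83 ± 0.65, EMP2 by 2.81 ± 0.69 and NCKAP5 by 2.73 ± 0.63, with edgeR adjusted p from 0.0315 to 0.0390. With each library's GC trend removed none of the 5 passed, and they stood at -2.04, -3.01, -1.61, -2.45 and -0.70, while camera called the list (adjusted p = 0.00038, but 0.89 with an estimated correlation). SEMA3B (1.18 ± 0.78) and AQP5 (1.91 ± 1.16) were higher in EGPA without passing. AGER, a standard type 1 marker, was at -0.26 ± 1.04 (adjusted p = 0.868), with 998, 236 and 10.6 CPM in EGPA replicates 1 to 3 and 287 to 672 CPM in the controls. Camera called the list (adjusted p = 0.0175), but not with an estimated correlation (adjusted p = 0.98) and not without EGPA replicate 3 (adjusted p = 0.58, in a range of 1.0e-09 to 0.58 over 23 alternatives), and fry did not call it (adjusted p = 0.24). The largest fall of any named gene was outside this list: AQP4, an aquaporin gene (chromosome 18, 26852038 to 26865818), had 0 counts in all 3 EGPA libraries and 2507 over the 4 controls, at least 271-fold lower against a floor of 3 counts over the EGPA group (adjusted p = 0.0206). The flavin monooxygenase gene FMO2 fell by 4.71 ± 0.64, the sodium channel gene SCN7A by 4.72 ± 0.91 and VEGFD, a lymphatic growth factor gene, fell by 4.89 ± 0.85. RGCC, ST8SIA6, PCDH15 and PARD6B fell by 4.84 to 4.90. With the GC trend removed AQP4 still passed (adjusted p = 0.0368), and these 7 genes did not: SCN7A stood at -2.03, FMO2 at -2.55, PCDH15 at -2.83, VEGFD at -3.33, ST8SIA6 at -3.35, PARD6B at -3.79 and RGCC at -4.78.

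Surfactant genes went different ways within the EGPA group. SFTPC, the surfactant protein C gene of alveolar type 2 cells, had 17463 and 5266 CPM in EGPA replicates 1 and 2, 1.72 CPM in EGPA replicate 3 and 397 to 3379 CPM in the controls, and its fitted difference did not pass (2.56 ± 1.67, adjusted p = 0.287). In lane 5, EGPA replicate 3 stood at 1.72 CPM and Control replicates 2 and 4 at 885 and 3379 CPM. The type 2 cell list was not called (camera adjusted p = 0.81). Its median log2 fold change was 1.85 and its mean 0.75, while the direction of the test was down. Its median difference from the control mean was 2.33 and 2.53 in EGPA replicates 1 and 2 and -4.85 in EGPA replicate 3, in log2 CPM.

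COL1A1, the gene of the type 1 collagen alpha 1 chain (chromosome 17, 50183289 to 50201632), rose by 5.40 ± 0.86 (edgeR adjusted p = 0.0291), with 12325, 16999 and 7611 CPM in EGPA replicates 1 to 3 against 99.9 to 594 in the controls. With the GC trend removed it stood at 4.02 ± 0.74 and did not pass (adjusted p = 0.0513). Of the 21 fibroblast and collagen matrix genes tested, 4 rose and none fell, and the list was not called (camera adjusted p = 0.158). The immediate early and heat shock list was called (camera adjusted p = 0.0175, adjusted p = 0.98 with an estimated correlation). Its median difference from the control mean was 0.98, 1.77 and 0.31 log2 CPM in EGPA replicates 1 to 3. In Control replicate 1 it was 1.265, so the groups overlapped. Of its 19 genes, 4 rose, and the median log2 fold change was 0.91. The 4 were the transcription factor genes EGR3 (3.20 ± 0.65) and EGR2 (2.86 ± 0.63) and the early response genes IER3 (4.14 ± 0.86) and IER2 (3.60 ± 0.82). With the GC trend removed they stood at 2.17, 3.34, 3.20 and 1.39, and none passed (edgeR adjusted p from 0.0567 to 0.139). With EGPA replicate 3 alone IER3 and IER2 stood at 1.18 and 0.71, and EGR3 and EGR2 at 3.09 and 2.51. No heat shock protein gene of the list was among these 4. This call ended without EGPA replicate 2 (adjusted p = 0.103), without EGPA replicate 3 (adjusted p = 0.0936), with EGPA replicate 3 alone (adjusted p = 0.282, median 0.19), after the GC trend was removed (adjusted p = 0.68, median -0.18) and after GC and length trends were removed (adjusted p = 0.70), the highest over 23 alternatives, of which the lowest was 0.00027.

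Most eosinophil granule, type 2 and regulatory genes fixed for reporting fell below the count filter of the main test. CLC, the Charcot-Leyden crystal protein gene, had 95 counts in EGPA replicate 3, 0 in EGPA replicates 1 and 2 and 1 over the controls. Because libraries differed in depth, means are given in normalized CPM, EGPA before control. EPX was at 1.46 ± 1.30 (SD, n = 3) and 0.264 ± 0.134 (SD, n = 4), from 10 counts in each group, PRG2 at 0.348 and 0.0971, and RNASE2 at 0.537 and 0.383. The eotaxin receptor gene CCR3 had 48 counts in EGPA, 43 of them in replicate 3, and 11 in control (2.85 and 0.305 CPM). CCL26, an eotaxin gene, had 36 counts, all in EGPA replicate 3, while CCL11 was at 0.215 and 0.469 CPM and CCL24 at 0.250 and 0.665. CCL17 was at 0.945 and 0.171 CPM, from only 3 and 7 counts. The macrophage chemokine gene CCL18 had 433 counts in EGPA, 421 of them in replicate 3, and 10 in control (19.6 and 0.257 CPM). IL5 was at 0.0716 and 0.629 CPM, from 2 and 23 counts, and IL13 at 0.277 and 0 CPM. Of the regulatory genes, IL10 had 95 counts in EGPA, all in replicate 3, and 16 in control (3.40 and 0.415 CPM), and CTLA4 was at 1.77 and 0.968 CPM. FOXP3 was at 6.49 ± 7.50 and 0.652 ± 0.233 CPM (SD, n = 3 and 4), from 28 and 25 counts. It stood at 3.61 and 15 CPM in EGPA replicates 1 and 2 and at 0.859 CPM in EGPA replicate 3, the latter within the controls. Without the filter its log2 fold change was 2.92 (edgeR adjusted p = 0.0829). CXCL13, a follicular chemokine gene, had 0 counts in every library, and the B cell gene MS4A1 was at 3.64 and 0.776 CPM. Tested without the filter, CCL18 (6.14 on the log2 scale, edgeR adjusted p = 0.0329) and CLC (6.53, adjusted p = 0.0424) passed, and the others among these genes with counts did not, with adjusted p from 0.0688 to 0.81. Of those tested, TGFB1 was at 1.40 ± 0.47 (edgeR adjusted p = 0.0776), the interleukin 5 receptor gene IL5RA at 2.26 ± 1.01 (adjusted p = 0.154) with 61.3 CPM in EGPA replicate 3, and the T cell gene CD3E at -0.07 ± 0.65 (adjusted p = 0.941). Of 18 tested genes on immunoregulatory cytokines and TGF-beta signalling, 2 rose and 1 fell (camera adjusted p = 0.57), and of 15 on regulatory T cells and immune checkpoints, 2 rose and 1 fell (camera adjusted p = 0.98).

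**Figure D4:**
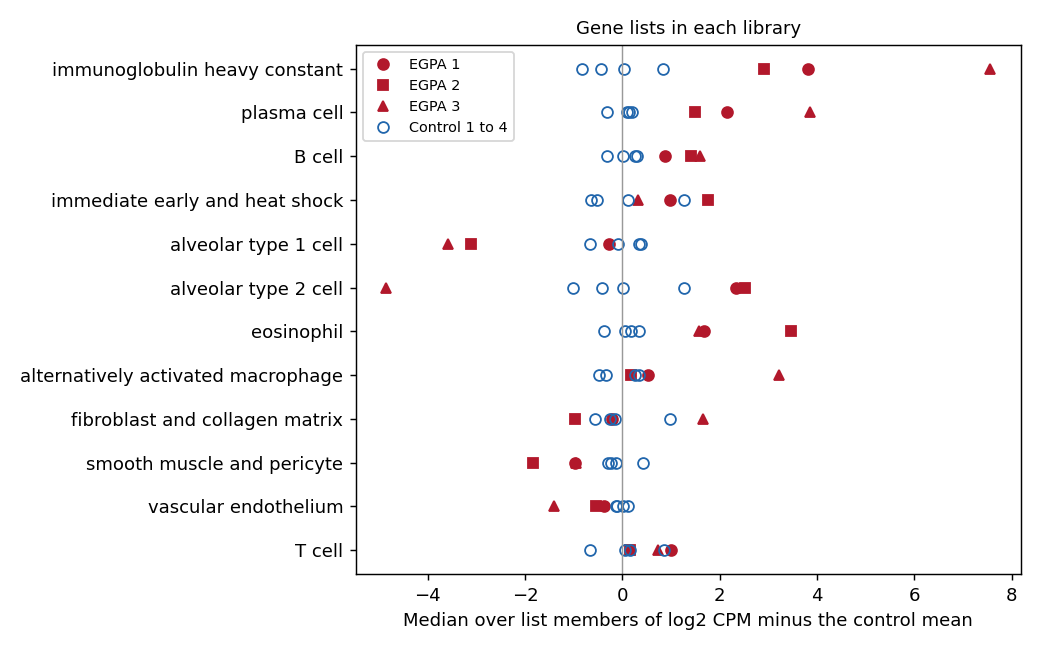
Median over the tested members of 12 gene lists of log2 CPM minus the control mean, 1 point per library, with EGPA replicates 1 to 3 as filled red circles, squares and triangles and controls as open blue circles. The heavy constant and plasma cell lists lay above 0 in all 3 EGPA libraries, while the alveolar type 2 list stood at 2.33 and 2.53 in EGPA replicates 1 and 2 and at -4.85 in EGPA replicate 3.

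Across all genes, 1748 of 14247 tested differed between EGPA and control lung (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1405 higher and 343 lower in EGPA. The groups did not overlap for 5150 genes (36.1%), against the 5.71% that chance gives on average over splits. Genes are not independent, and deviations of all 3 EGPA libraries rose with GC content, so a shared trend can part many genes at once. The excess does not by itself measure a difference due to disease. Besides immunoglobulin and plasma cell genes, the 10 largest rises held ZFHX3 (7.98 ± 1.83) and FOXB2, GSG1L, CXXC4, HOXC12 and STUM (7.47 to 9.60). Each of the latter 5 had at least 248 CPM in EGPA replicates 1 and 2, where the ZFHX3 share was 47.4% and 66.9%, and at most 34.6 CPM in EGPA replicate 3. The median GC content was 62.0% for the genes that rose, 44.0% for those that fell and 50.2% over all tested genes, and log2 fold change correlated with GC content (Spearman 0.728 across genes). With each library's GC trend removed, a setting chosen after seeing the data, 27 genes passed (21 higher, 6 lower), 23 of them called before in the same direction, among them IGHE, POU2AF1, FCRL5, FCER2, PIM2 and AQP4. IGHG4 then stood at 10.51 ± 2.02 (adjusted p = 0.0513, in a range of 2.9e-16 to 0.104 over its 24 alternatives). The median log2 fold change over all tested genes was -0.13 with TMM scaling, -0.23 with DESeq2 size factors and -0.91 with library totals, under which no gene passed (2994 at an unadjusted p under 0.05).

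The number of genes called depended on each library. It was 84 without EGPA replicate 1, 1 without EGPA replicate 2, 9038 without EGPA replicate 3 and 1 without Control replicate 1. Without Control replicates 2, 3 or 4 edgeR called 0 genes, with 3347, 3436 and 3386 at an unadjusted p under 0.05, so no named gene kept its call when each library was left out in turn. With only EGPA replicate 3 kept, 1249 genes passed, 673 higher and 576 lower. With lane number as a factor the count was 754, 377 in each direction, and 299 of these were called in the main fit in the same direction. On log2(TPM + 1) limma called 161 higher and 1571 lower. Camera called 5 of 41 lists, the 5 described above as called, 17 without EGPA replicate 1, 12 without EGPA replicate 2, 2 without EGPA replicate 3 and 8 without Control replicate 3.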

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

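All tests of explanations below were chosen after the results they bear on had been seen.

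Of 52 sets of 4 control values examined, 3 held a control far from the other 3, where chance gives about 1 in 20. SCEL was lowest in Control replicate 1, at 72.3 CPM against 171 to 191 CPM. TGFB1 was lowest in Control replicate 2, at 29.6 CPM against 39.8 to 40.9 CPM. SFTPC was highest in Control replicate 4, at 3379 CPM against 397 to 885 CPM. Transcripts matched to no gene, which no comparison used, held 0.694% of the counts in EGPA replicate 1 and 0.572% in EGPA replicate 2, above the highest control at 0.438%.

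The IGHG4 share of IgG counts was higher in EGPA. Counting error from unequal IgG depth was argued against by thinning every library to 828 IgG counts. The lower end of the 95% range of the gap between the lowest EGPA and the highest control share, over 1000 thinnings, was then 37.4 percentage points. The thinning drew from the finished estimates, so it could not show how depth affects the division of shared reads. A smooth trend with gene GC content shifts the 4 IgG genes nearly alike, since they had 61.1% to 61.6% GC. Its removal could therefore hardly move the difference in log2 IGHG4 over IGHG1, which was 5.52 as counted and 5.46 with the trend removed. These values are thus no separate evidence against a GC trend. Within lane 5 the groups stood at 46.5% against 5.48% and 1.96%, while lanes 3 and 4 held a single group each. What stays open is how the estimation divided reads shared between the IgG genes, a difference between lanes 3 and 4, and a higher proportion of IgG4-expressing cells in EGPA lung, none of which was tested. The exact test used for the share, which doubles the smaller tail, could not pass 0.05.

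EGPA replicates 1 and 2 stood apart from the other 5 libraries along a first component holding 73.3% of the variance. Shallow depth alone, the counts lost to ZFHX3 included, was argued against: controls thinned to the 585234 counts of EGPA replicate 2 outside ZFHX3 still correlated with the other controls at 0.918 or more, against 0.391 and 0.498 for the 2 EGPA libraries. With the smooth GC trend removed the better of the pair reached 0.756, below the 0.831 of EGPA replicate 3. Removing a smooth trend cannot bring back genes whose counts were lost. EGPA replicate 2 had 8149 genes with at least 5 counts, against 10074 to 10721 in the thinned controls. A GC trend as the whole cause therefore stays open. Also open are a further difference in RNA quality or library preparation and a biological difference between these lungs, neither of which was tested. The former may go with the lane (both libraries were in lane 3, with no other library).

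The genes called between EGPA and control carried the same trend. Removing it moved the median log2 fold change of the genes that rose from 2.86 (median SE 0.66) to 1.20 (0.46), and that of the genes that fell from -3.04 (0.70) to -1.80 (0.60). Library by library, the share of the median difference from the control mean that was left for the risen genes was at most 45.6% in EGPA replicates 1 and 2 and 65.3% in EGPA replicate 3, and for the fallen genes it was 40.6%, 35.7% and 84.8% in EGPA replicates 1 to 3. Less than 50% was left in EGPA replicates 1 and 2 and more in EGPA replicate 3, so over the 3 libraries the trend and a real difference cannot be told apart as the larger part, in either direction. After removal 1349 of 1404 risen genes with a GC value and 333 of 343 fallen genes kept their sign, and 846 and 241 had an unadjusted p under 0.05. Calls thus ended partly with smaller folds and partly at the adjustment over all genes, and some ended without a smaller fold (SPP1 went from 4.31 to 6.09, adjusted p = 0.0513). Only the real split, 1 of the 35 splits of the 7 samples, called 1748 genes. The highest other called 0, in the 14 others that kept EGPA replicates 1 and 2 together as in the 20 that parted them. A share of 1 in 35 is the smallest these splits allow. Most other splits parted EGPA replicates 1 and 2 or put them in the larger group. They thus held the pair's large difference from the other libraries within a group, which by itself leaves few genes to call. Only the splits that joined the pair with a single control were like the real one. They are too few to weigh chance, which was not excluded. Nor can the splits tell disease from structure, since EGPA replicates 1 and 2 shared a lane and a strong GC trend. The count of 1748 was itself unstable, at 0 or 1 in edgeR when any control was left out (3347, 3436 and 3386 genes at an unadjusted p under 0.05 without Control replicates 2, 3 and 4). For the lists chance could not be excluded either: 30 of 35 splits called at least the real 5, and the highest other called 25. The split along lane 5 also called 5. The 20 splits that parted EGPA replicate 1 from EGPA replicate 2 called 7 to 25, which points to the structure of the samples. Taken singly, the camera p of the B cell list was as small in 1 of the 35 splits, the real one (unadjusted p = 0.0025, the smallest other 0.0039), that of the heavy constant list in 4, of the plasma cell list in 7 and of the alveolar type 1 and immediate early lists in 16 each.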

How the results depend on the processing

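No paired analysis was possible because the labels carry no replicate numbers that tie samples across groups. Settings named as GC content, ZFHX3 or EGPA replicate 3 alone were chosen after seeing the data. The count of 1748 genes stayed within 1.5 times under DESeq2 size factors, both low-count filters, both settings that left out gene classes, the length offset, robust fitting, ZFHX3 left out, log2(TPM + 1) and EGPA replicate 3 alone. Totals alone hide that log2(TPM + 1) called 1732 genes, 161 higher and 1571 lower, and shared 457 with the main fit in the same direction, and that EGPA replicate 3 alone called 1249 and shared 440. It was 0 with library totals (2994 at an unadjusted p under 0.05 in edgeR), 754 with lane as a factor, 8212 with limma-voom quality weights, 92 on log2(TPM + 0.1), 4037 on log2(TPM + 1) with a minimum TPM, 4063 with the DESeq2 Wald test, 938 for a fold of at least 1.5, 27 with the GC trend removed and 197 with GC and length trends removed, and it ran from 0 to 9038 when a replicate was left out. The 5 called lists became 10 with library totals, 8 without a low-count filter, 20 with lane as a factor, 9 on log2(TPM + 1), 8 on log2(TPM + 0.1), 9 with a minimum TPM, 9 with GC removed, 9 with GC and length removed, 22 with EGPA replicate 3 alone, 2 with fry and 0 with an estimated correlation, and 2 to 17 when a replicate was left out. The plasma cell and heavy constant lists kept their camera call at the preset correlation in each setting that could test them.

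The IGHG4 share difference stayed between 44.05 and 49.63 percentage points in every setting on the percent scale, and the immunoglobulin share stayed higher in EGPA in all settings run, from 0.189 to 9.43 points. The lambda difference reversed to -18.4 points with EGPA replicate 3 alone and ran from -1.37 to 17.9 when a replicate was left out. SFTPC reversed to -10.26 with lane as a factor and to -9.56 with EGPA replicate 3 alone. With EGPA replicate 3 alone, the libraries in which SFTPC and lambda were high are left out. With lane as a factor the SFTPC difference rested on lane 5, the only lane with both groups. There EGPA replicate 3 stood at 1.72 CPM and Control replicates 2 and 4 at 885 and 3379 CPM. For the other changes the cause was not tested. For named genes, 780 of 1175 values under alternatives kept direction and side of the threshold, 381 lost the call, 12 gained one and 2 reversed. AQP4 and POU2AF1 passed in 18 of the 19 settings that kept all libraries or dropped a pair, FCER2, PARD6B and PIM2 in 17 of 19 and IGHG4 in 15 of 17. Of the named genes below the count filter, FOXP3 passed with the DESeq2 Wald test (adjusted p = 0.0137) and without EGPA replicate 3 (adjusted p = 0.0031), CCR3 with the Wald test (adjusted p = 0.0256), IL5, lower in EGPA, on log2(TPM + 1) with and without a minimum TPM, IL10 with EGPA replicate 3 alone, CLC in 2 of 4 settings that tested it and CCL18 in 5 of 7. FOXP3 rested on 9, 11 and 8 counts in EGPA replicates 1 to 3 and 25 in control. At 0.859 CPM, EGPA replicate 3 lay within the controls. IL5 rested on 2 counts in EGPA and 23 in control, and edgeR without the filter gave an adjusted p of 0.255. Depth limited EGPA replicate 2 most. In the simulation 52% of genes changed 16-fold and 14% of those changed 8-fold were called. Few genes were changed there, so these shares do not give the power in the real libraries.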

Other observations

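Some macrophage genes outside the named set were higher in EGPA lung, although no macrophage list was called in the main fit. The genes in this paragraph were chosen after their values were seen. Of 18 monocyte and macrophage genes tested, 5 rose and none fell (C1QB by 2.63 ± 0.66, C1QC by 2.37 ± 0.62, CD14 by 2.29 ± 0.60, ITGAM by 2.18 ± 0.51 and CSF1R by 1.87 ± 0.48, log2 ± SE), and the list was not called (camera adjusted p = 0.247); LYZ was at -3.17 ± 1.11 and S100A4 at -1.42 ± 0.58, and neither passed. Of 13 genes of alternatively activated macrophages, 3 rose over all genes and 8 when adjusted over the list alone, among them the scavenger receptor genes STAB1 (3.60 ± 0.63) and MARCO (2.32 ± 0.66) and the lectin gene CD209 (4.52 ± 1.20, and 1.31 with an adjusted p of 0.194 without EGPA replicate 3), with a camera adjusted p of 0.0816. This list's median difference from the control mean was 0.53, 0.18 and 3.22 log2 CPM in EGPA replicates 1 to 3. With the GC trend removed camera called it at the preset correlation (adjusted p = 0.0139). The monocyte and macrophage list (adjusted p = 0.52) and the alveolar macrophage list (adjusted p = 0.98) were then not called. Of 13 granuloma and giant cell genes, SPP1, TREM2 and CYP27B1 rose by 3.41 to 4.31 and the lipoprotein lipase gene LPL fell by 3.25 (camera adjusted p = 0.218). Of 7 tested eosinophil genes, the eosinophil lectin gene SIGLEC8 (4.17 ± 0.80) and SMPD3 (2.57 ± 0.64) rose (camera adjusted p = 0.0949). Camera at the preset correlation called the eosinophil list with the GC trend removed (adjusted p = 0.0285), although no member then passed singly. CLC, EPX, PRG2 and RNASE2 were below the count filter and not among the 7. In the main fit the list was not called with an estimated correlation (camera adjusted p = 0.89) or by fry (adjusted p = 0.133). The type 1 collagen partner gene COL1A2 rose by 2.54 ± 0.66, COL3A1 by 3.34 ± 0.86 and COL5A1 by 3.14 ± 0.60, and the inhibitory receptor gene LILRB4 rose by 3.94 ± 0.78. These rises and falls passed an edgeR adjusted p of 0.05, and none of these genes passed once the GC trend was removed, although each kept its direction. The log2 fold change was then larger for SPP1 (6.09), and smaller for the others: CD209 (4.40), SIGLEC8 (3.996), LILRB4 (3.55), TREM2 (3.27), COL3A1 (2.92), LPL (-2.88), STAB1 (2.38), MARCO (2.15), COL1A2 (2.14), CD14 (1.995), COL5A1 (1.82), C1QB (1.71), CYP27B1 (1.69), ITGAM (1.61), C1QC (1.38), CSF1R (1.19) and SMPD3 (0.87).

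Vessel and muscle genes included several that fell. Of 20 vascular endothelial genes tested, 4 fell and none rose: TEK by 2.55 ± 0.55, EDNRB by 2.35 ± 0.56, HPGD by 4.55 ± 0.83 and TMEM100 by 3.70 ± 0.70, while the pan-endothelial gene VWF was at 0.92 ± 0.54. Of 14 smooth muscle and pericyte genes, ACTG2 fell by 3.61 ± 0.65 and CNN1 by 2.97 ± 0.66. Camera did not call the endothelial list (adjusted p = 0.176) or the muscle list (adjusted p = 0.0949). With the GC trend removed it called both (adjusted p = 0.00011 and 0.00059) but neither with an estimated correlation (adjusted p = 0.685 for each), and fry then called the muscle list (adjusted p = 0.0471) but not the endothelial list (adjusted p = 0.0689). Of the 6 genes that fell, only CNN1 then passed (-4.07, adjusted p = 0.0368). ACTG2 stood at -3.60, HPGD at -3.13, TMEM100 at -2.01, TEK at -1.16 and EDNRB at 0.06.

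A set of 84 transcripts had over 50 CPM (outside ZFHX3) in both EGPA replicates 1 and 2 and under 0.5 counts in each of the other 5 libraries. The highest number for any other pair of libraries was 2. With FOXB2, GSG1L, CXXC4, HOXC12 and STUM, whose counts ran parallel to those of ZFHX3, they mark what these libraries shared, and no source was tested.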
